A study of Arabidopsis thaliana with 13 samples.

How the data were processed

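Root RNA of 10-day-old Arabidopsis thaliana plants was hybridised to 13 Affymetrix ATH1 arrays. The groups were Col-0 (n = 3), Ler (n = 3), clv1-15 in the Ler background (n = 3) and the CLE3 overexpression lines 12-1 and 17-3 in the Col-0 background (n = 2 each). Per the labels, plants grew at 22 °C under 16 h light and 8 h dark on MGRL medium with 0.1 mM KNO3 and 1% sucrose, and each array is a biological replicate. Whether replicates came from separate cultures or days is not stated. Per the submitters' processing notes, the arrays were processed with MAS5, with no version given.

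The deposited values are linear intensity (MAS5 signal), scaled per array: with 2% trimmed at each end, the mean was 500.0 on every array. Detection calls were not used here. The number of arrays, not a count, limits the precision. No pair of arrays was identical, and 0 columns lacked a sample.

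Each value was taken as log2(signal + 16). The 64 control probe sets and the lowest 30% of the others by mean over all arrays were left out, which left 15922 of 22810 probe sets. limma 3.58.1 in R 4.3.3 fitted the 5 groups together, with a moderated test (eBayes with a trend) and Benjamini-Hochberg adjustment over all tested probe sets in each comparison. A probe set passed the test at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from limma, and errors of signals are standard deviations (SD). The CLE3ox effect is the mean of both lines minus Col-0. Its SE and p value rest on the spread of arrays within groups and leave out the difference between the lines. All 3 Col-0 arrays serve both lines and both wild types' comparison, and the Ler arrays serve clv1-15 and that comparison. The CLE3ox and clv1-15 effects share no arrays.

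The groups, comparisons, threshold, gene lists and the rule for named genes were fixed before the data were examined. The rule names the 10 highest rises and 10 deepest falls per main comparison among single-gene probe sets past the threshold whose arrays do not overlap between the sides, and 5 of each for Col-0 against Ler, line against line and the difference of effects. It also names the 5 with the smallest larger p in each pattern of genes called in both CLE3ox and clv1-15, and up to 4 members of a gene list. CLE3, CLV1 and ERECTA were to be named in any case.

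Gene names come from the platform's probe table, matched to the TAIR10.1 annotation by gene ID. Of the probe sets, 13513 had 1 gene, 503 had several and 8730 had none, and 13436 of the single-gene sets matched the annotation. No probe set is named CLE3, CLV1 or ERECTA (0 each), so no value could be tied to these genes by name. Whether any probe set without a single gene name measures them was not examined. Of 403 members of the 24 fixed lists, only 41 had a named probe set. After this coverage was seen, and before any expression test, 5 lists were added: class III peroxidases, cytosolic ribosomal proteins, CC-type glutaredoxins, extensins and NPF transporters. Plastid-encoded genes and families of at least 8 genes sharing a symbol stem were added as well.

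Lists with at least 3 measured probe sets (38, of them 3 fixed) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists in each comparison, with an estimated correlation and fry beside it. camera asks whether a list moved relative to the other genes.

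The fit was tested on simulated data, in which 50 probe sets per size were changed. At a log2 change of 0.5 it recovered 68% for CLE3ox, 80% for clv1-15 and 58% for Col-0 against Ler. At a log2 change of 1 it recovered 100%, 100% and 98%. Of 15722 unchanged probe sets, 19, 12 and 6 were called. Both clv1-15 against Ler and Col-0 against Ler set 3 arrays against 3 in the same fit. The gap between 80% and 58% therefore reflects the random draw of 50 probe sets, not a property of either comparison. Far fewer probe sets were changed than the 2434 and 7215 that passed in these comparisons in the real data, so recovery there may differ. The simulated noise was independent between arrays and probe sets, so these numbers leave out any batch or other deviation shared by arrays.

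Alternatives were other pseudocounts, filters, between-array scalings, variance priors, array weights, a block for replicate number, each comparison's groups alone and leaving out each array in turn. Where this left 1 array in a group, that array is assumed to vary like the other groups. Deviations of arrays with the same replicate number correlated at r = 0.01 to 0.19 for clv1-15 and Ler and at 0.31 for lines 12-1 and 17-3. For the lines and Col-0 they correlated at 0.24 and 0.18 for number 1 and at -0.18 and -0.19 for number 2. After the data were seen, a spike-in batch was defined from the bioD spike-in signal, divided at 3500; no label gives a hybridisation date. The second arrays of both CLE3ox lines and the third Col-0 array lay between 3894.3 and 4092.7, and the other 4 arrays of that background between 2765.1 and 3091.9. That batch was run as a block and within each batch. Ranges of adjusted p over alternatives cover the planned ones and leave out these batch fits.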

Results

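Whole-root RNA was compared in 5 genotypes of Arabidopsis thaliana on 13 arrays. CLE3 belongs to the CLE family of small secreted signalling peptides, and CLAVATA1 (CLV1) is a leucine-rich repeat receptor kinase that perceives peptides of this family. Lines 12-1 and 17-3 (CLE3ox, n = 2 arrays each) overexpress CLE3 in the Col-0 background, with Col-0 (n = 3) as their wild type. The mutant clv1-15 (n = 3) was compared with its own background, Ler (n = 3), which is short for Landsberg erecta. The medium held 0.1 mM nitrate, a low supply. The median signal per array lay between 189.8 and 200.1, and the highest signal between 23436.5 and 28448.7. Pearson's r across probe sets between replicates of a group was 0.9867 to 0.9934; genes are not independent replicates. The first principal component held 67.6% of the variance and separated the 7 arrays in the Col-0 background from the 6 in the Ler background.

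The first comparison asked which root transcripts differ when CLE3 is overexpressed. The small heat shock protein gene AT1G53540 rose by a log2 fold change of 2.12 ± 0.27 (SE, adjusted p = 0.00037). Its signal was 50.1 ± 16.7 (SD, n = 3) in Col-0, 144.7 ± 7.4 (n = 2) in line 12-1 and 479.7 ± 22.8 (n = 2) in line 17-3. Each line alone against Col-0 gave 1.31 in line 12-1 (limma adjusted p = 0.12, not past) and 2.94 in line 17-3 (8.3e-05). The SE of 0.27 does not cover this difference between the lines. AT4G33720, of the pathogenesis-related 1-like protein family, rose by 2.03 ± 0.20 (adjusted p = 2.1e-05) from a low signal of 43.5 ± 5.5. ATC, the Arabidopsis homologue of the flowering regulator CENTRORADIALIS, rose 3.46-fold (adjusted p = 8.3e-06), from 160 ± 40.8 in Col-0 to 470.6 ± 9.8 and 720 ± 50.4 in the lines. The other 7 of the 10 highest rises with a gene name were ATHSP22.0, AT1G54050 and AT5G37670, which encode further small heat shock proteins, the hydrolase-like genes AT3G15650 (2.85-fold, adjusted p = 8.3e-06) and AT1G52700 (2.57-fold), AT5G10695, and rpoA of the plastid RNA polymerase. In line 12-1 alone ATHSP22.0, AT1G54050 and AT5G37670 did not pass (limma adjusted p = 0.054, 0.058 and 0.088), while all of them passed in line 17-3. With the lines as 1 group of 4 arrays AT1G52700 lost its call (adjusted p = 0.05, with a range of 0.00021 to 0.05 over the alternatives set in advance).

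AT3G12900, which encodes scopoletin 8-hydroxylase of coumarin synthesis, had a log2 fold change of -1.86 ± 0.30 (adjusted p = 0.0028), from a signal of 512 ± 120.1 in Col-0 (n = 3) to 120.9 ± 5.9 and 133.9 ± 0.1 in lines 12-1 and 17-3 (n = 2 each). The berberine bridge enzyme-like oxidase genes AT1G26410, AT1G26380 and AT1G26390 were 3.09-fold, 2.93-fold and 2.79-fold lower (adjusted p = 0.00011, 0.00017 and 3e-05). AT2G38870, a protease inhibitor gene of the PR-6 family, fell from 2310.8 ± 248 to 1049.7 ± 117.1 and 1124.5 ± 27 (adjusted p = 3.4e-06). The others of the 10 deepest named falls were AT3G55790, the cupredoxin gene AT3G60270, the extensin-like gene AT1G26240, the germin-like gene AT5G38910 and the S-locus lectin kinase gene AT1G61500, with log2 fold changes between -2.02 and -1.20. With a pseudocount of 1 AT3G12900 and AT1G26380 lost their calls (adjusted p = 0.051 and 0.052; 3.8e-05 to 0.051 and 8e-07 to 0.052 over the alternatives set in advance).

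In all, 389 of 15922 probe sets passed the limma test in CLE3ox, 168 higher and 221 lower, of which 51 changed at least 2-fold. A grouping of the arrays by spike-in signal, called the spike-in batch here, was looked at after the data were seen. With it as a block 519 passed, among them all 389. Within the first batch 66 passed, on 1 array per line and 2 Col-0 arrays. Within the second 54 passed, on 1 array per line and 1 Col-0 array, so that all of the spread there is borrowed from clv1-15 and Ler. Of the 45 named calls 28 were lost in the first batch and 30 in the second, with 0 changes of sign. The count was 236 without the second array of line 12-1, 228 without the first Col-0 array and 206 without the last Col-0 array. The call on rpoA ended without any 1 of 5 arrays (the second of either line or any Col-0 array; adjusted p 0.055 to 0.09, against 0.0046 to 0.1 over its alternatives set in advance).

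Among the fixed lists, 16 had a measured member, with 32 measured probe sets in all; in CLE3ox 2 rose, 1 fell and 29 did not pass, while 12 passed when adjusted over the list alone. CLE44, which encodes a CLE peptide of vascular development, rose by 0.86 ± 0.12 (adjusted p = 0.00078). It was 1 of 4 measured CLE and CLAVATA components past the threshold (2 adjusted over the list alone), and the list moved up (camera adjusted p = 0.0016; adjusted p = 0.21 with an estimated correlation). SWEET11, a sucrose transporter gene of phloem loading, rose by 0.92 ± 0.18 (adjusted p = 0.0097), 1 of 2 measured phloem genes (1 adjusted over the list alone). AT3G13610, which encodes the feruloyl-CoA 6'-hydroxylase of coumarin synthesis, had a log2 fold change of -0.43 ± 0.08 (adjusted p = 0.0073), 1 of 2 measured iron-deficiency genes (2 adjusted over the list alone). Without the last Col-0 array its adjusted p was 0.05, and its range over the alternatives set in advance 0.0044 to 0.05.

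None of the measured members of the other fixed lists passed over all genes in CLE3ox. The low-nitrate transporter gene NRT2.5 had a log2 fold change of -0.29 ± 0.16 (adjusted p = 0.45). It was the 1 measured member of the 25 in the nitrate uptake and assimilation list. The auxin conjugation gene GH3.3 had 0.64 ± 0.19 (adjusted p = 0.098), in an early auxin list with 0 of 4 past and 3 adjusted over the list alone (camera adjusted p = 0.55). The lateral root list had 0 of 3 past (0 adjusted over the list alone; camera adjusted p = 0.73), with -0.18 for LBD16. The root hair expansin genes EXPA7 and EXPA18 had -0.31 (adjusted p = 0.072) and -0.27 (0.18), and both passed adjusted over the list alone. Cytokinin response (RR16, -0.06), salicylate and camalexin defence (WRKY53, 0.05), secondary wall (GUT2, -0.10), cell cycle (PRL, 0.10), clock (GI, 0), touch and wounding (STZ, -0.15) and glucosinolate (BCAT4, 0.27) had none past, nor any adjusted over the list alone. Of the 11 to 18 members of each of these lists only 1 or 2 were measured, so these values do not speak for the lists as a whole. Flavonoid synthesis (UGT78D2, -0.43) and the shoot markers LHCB4.1 (0.25) and RCA (0.21) each had 1 adjusted over the list alone. The lists of ammonium and organic nitrogen transport, nitrogen regulators, phosphate starvation, sulfur starvation, jasmonate and ethylene defence, endodermis and suberin, heat shock and hypoxia had no measured member.

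Of the 38 lists tested in CLE3ox, camera called 7, 4 up and 3 down. No call held after adjustment with an estimated correlation. The 63 measured plastid-encoded probe sets were higher by a median of 0.21 (camera adjusted p = 3.7e-10; adjusted p = 0.10 with an estimated correlation), with 3 rises, those of rpoA, rps4 and psbF. The 106 cytosolic ribosomal protein probe sets had a median of 0.09 (camera adjusted p = 1.8e-07; adjusted p = 0.21 with an estimated correlation), with 0 past the threshold. The 10 extensins had a median of -0.38 (camera adjusted p = 7.1e-05; adjusted p = 0.29 with an estimated correlation), and AT1G26240 was the 1 that fell. The RPS symbol family went up (camera adjusted p = 0.00038, adjusted p = 0.21 with an estimated correlation), and 1 of its 7 members, rps4, rose. That gene is also among the plastid-encoded rises above, so these lists overlap and their calls are not separate evidence. The UGT glycosyltransferases (camera adjusted p = 0.023; adjusted p = 0.27 with an estimated correlation) and the EXPA expansins (camera adjusted p = 0.033; adjusted p = 0.21 with an estimated correlation) went down. In the UGT family UGT72E2 was the 1 of 30 that fell, and among the expansins EXPA15 was the 1 of 7. Class III peroxidases (1 rose and 3 fell of 41; camera adjusted p = 0.21), CC-type glutaredoxins (1 rose of 8; 0.98) and NPF transporters (0 of 21; 0.83) were not called. Single members are fragile: without 1 array rps4 lost its call in 4 cases (the second array of either line, the second or last of Col-0; adjusted p 0.061 to 0.084) and psbF in 5 (all but the first array of line 17-3 and the last of Col-0; 0.099 to 0.20). UGT72E2 lost it in 4 (the second array of either line, the first or last of Col-0; 0.051 to 0.064) and EXPA15 in 2 (the first or second of Col-0; 0.05 to 0.066). Over the alternatives set in advance these ran from 0.013 to 0.084, 0.012 to 0.20, 0.0072 to 0.064 and 0.0028 to 0.066. All 4 peroxidase calls ended without some array: AT5G39580 without any 1 of 7 (0.052 to 0.18), AT1G71695 without any 1 of 5 (all but the first array of line 17-3 and the first of Col-0; 0.08 to 0.18), AT3G21770 without the first or last Col-0 array (0.05 to 0.061) and AT1G14550 without the first (0.05). The glutaredoxin gene AT1G06830 lost its call without the second array of line 12-1 or the first of Col-0 (0.061 to 0.084).

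**Figure D1:**
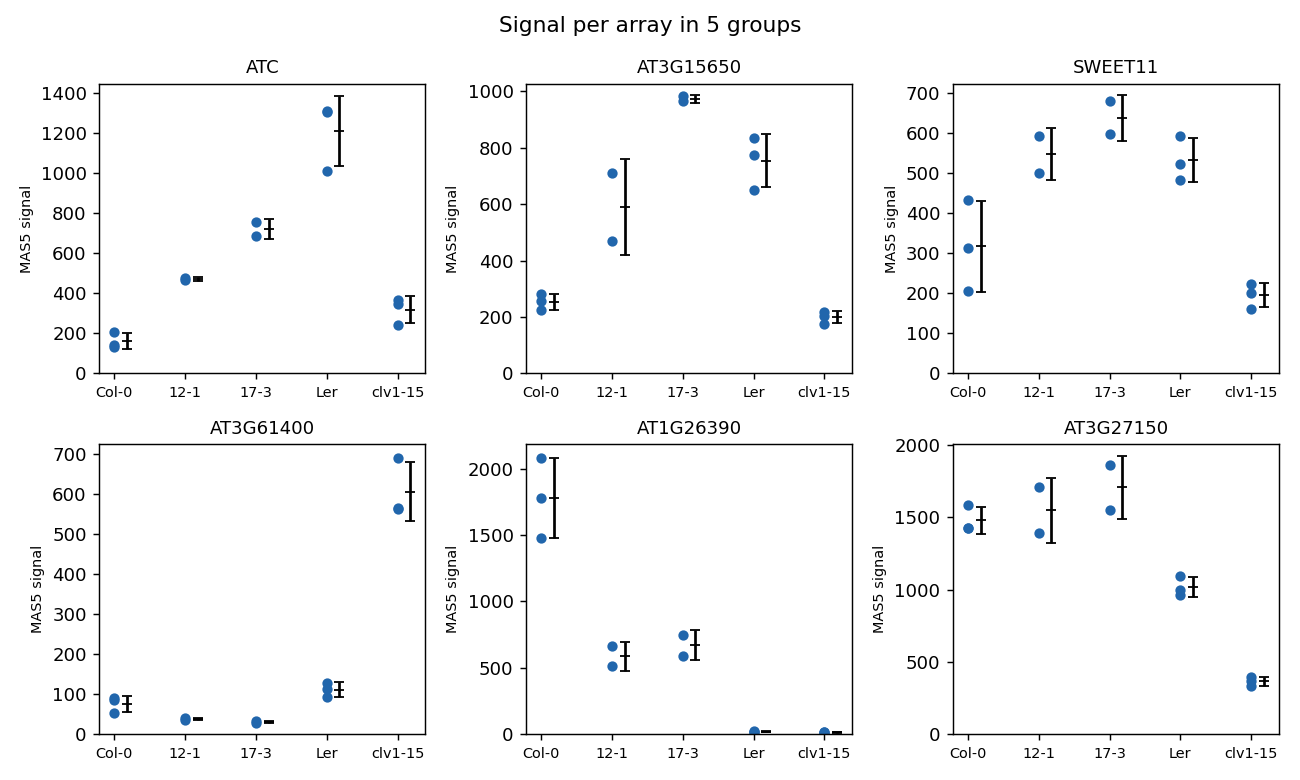
MAS5 signal (vertical axis, linear, starting at 0) of 6 named genes in each array (points) of the 5 groups, with group mean and SD (bars). ATC, AT3G15650 and SWEET11 are higher in both CLE3ox lines than in Col-0 and lower in clv1-15 than in Ler, and AT1G26390 averages 1781.9 in Col-0 and at most 15.5 in Ler and clv1-15.

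The lines were also compared each with Col-0 and with one another. The hydrolase-like gene AT1G52700 was higher in line 17-3 than in line 12-1 by 1.44 ± 0.25 (adjusted p = 0.018), and the small heat shock protein gene AT1G52560 by 1.18 ± 0.17 (adjusted p = 0.0056). AT2G33850 (1.11 ± 0.15, adjusted p = 0.0049), the RING-type gene AT5G60250 and AT5G10695 were higher in line 17-3 as well. AT3G29430, a geranylgeranyl diphosphate synthase-like gene, was lower (-1.02 ± 0.18, adjusted p = 0.018), as were AT5G26080, AT5G57840 and AT5G54370. Line 12-1 differed from Col-0 in 69 probe sets (14 higher, 55 lower) and line 17-3 in 528 (266 higher, 262 lower). Of these, 59 passed in both lines with the same sign, 11 higher and 48 lower. Independent lists would share 2.3, but the lists are not independent, since both lines are set against the same Col-0 arrays.

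Directly compared, the lines differed in 42 probe sets, 35 higher and 7 lower in line 17-3. Without the first array of line 17-3 they differed in 46, 25 higher and 21 lower, so the balance of directions rests on that array. The fold changes of the lines against Col-0 correlated across probe sets at r = 0.68 (Spearman 0.57), where the shared Col-0 arrays alone give 0.40 in simulation. Their covariance was 0.0345, against 0.0083 in simulation. The simulated noise is independent between arrays, so the spike-in batch and other deviations shared by arrays are not in it. The count for line 12-1 was 25 without its second array, 43 without the second and 38 without the last Col-0 array. For line 17-3 it was 186 without its second array, 347 without the first and 343 without the last Col-0 array. The count between lines was 22 without the first and 14 without the second array of line 12-1, and 13 without the second array of line 17-3. All 9 named genes of this comparison lost their call without the first array of line 12-1, and all 9 without the second array of line 17-3. Leaving out either of the other arrays ended 5 of the calls. With the spike-in batch as a block, 99, 686 and 52 probe sets passed in line 12-1, in line 17-3 and between the lines.

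The comparison of clv1-15 with Ler asked which root transcripts differ when CLV1 is mutated. AT3G61400, a 2-oxoglutarate-dependent dioxygenase gene, rose by 2.30 ± 0.17 (adjusted p = 6.9e-07), from a signal of 110.8 ± 18.1 (SD, n = 3) to 604.9 ± 74 (n = 3). AT3G15450 and AT4G27450, related to aluminium-induced proteins, rose by 2.17 ± 0.20 and 1.37 ± 0.15 (adjusted p = 6.5e-06 and 4.1e-05), and the pectin lyase-like gene AT5G14650 by 1.89 ± 0.13 (adjusted p = 2.6e-07). The extensin-like genes AT3G54580, AT5G06630, AT4G08410, AT5G19810 and HRGP1 rose by 1.23 to 1.56. AT4G33720 rose 2.74-fold, from 2271.7 ± 664.3 to 6121.9 ± 888.8.

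OCT1, which encodes an organic cation and carnitine transporter, was the deepest named fall (-2.13 ± 0.13, adjusted p = 1.5e-07), from 494.2 ± 58.1 in Ler to 101.3 ± 21.1 in clv1-15 (n = 3 each). The defensin gene PDF2.1 (-1.99), ATC (-1.89), AT3G15650 (-1.84) and the small heat shock protein gene AT1G53540 (-1.75) fell by nearly as much. AT3G27150, a kelch-repeat F-box gene targeted by the shoot-to-root microRNA miR2111, fell from 1017 ± 68.4 to 363.1 ± 31.3 (adjusted p = 3.4e-07). The other falls among the 10 deepest with a name were AT2G16005, AT1G33340, AT2G23910 and the jacalin lectin gene AT1G19715, between -1.79 and -1.39.

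In clv1-15 2434 probe sets passed the limma test, 1096 higher and 1338 lower, and 130 changed at least 2-fold. With each array centred on its median 2349 passed, 1309 higher and 1040 lower, so which direction holds more genes depends on the scaling. The count was 1503 without the first Ler array.

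Among the 32 measured members of fixed lists, 6 rose and 3 fell in clv1-15, and 14 passed when adjusted over the list alone. The auxin conjugation genes GH3.3 (0.98 ± 0.20, adjusted p = 0.0047) and WES1, also known as GH3.5 (0.73 ± 0.09, adjusted p = 7.7e-05), rose, 2 of 4 early auxin genes (2 adjusted over the list alone; camera adjusted p = 0.17). The root hair gene EXPA18 rose by 0.68 ± 0.10 (adjusted p = 0.00059), 1 of 2 (2 adjusted over the list alone). SWEET11 was lower by -1.38 ± 0.19 (adjusted p = 0.00024), 1 of 2 phloem genes (2 adjusted over the list alone), and the flavonoid glycosyltransferase gene UGT78D2 by -1.09 ± 0.14 (adjusted p = 0.00013), 1 of 2 (1 adjusted over the list alone). The shoot markers RCA (0.49 ± 0.12, adjusted p = 0.014) and LHCB4.1 (0.43 ± 0.09, adjusted p = 0.0066) rose along with these groups, 2 of 2 also adjusted over the list alone. The lateral root gene PUCHI (0.47, adjusted p = 0.039) rose, 1 of 3 (2 adjusted over the list alone; camera adjusted p = 0.17), and the defence gene WRKY53 fell (-0.65, adjusted p = 0.023), 1 of 1.

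Some of these calls rest on single arrays. The call on PUCHI ended without any 1 of the 6 arrays (adjusted p 0.053 to 0.12; 0.022 to 0.12 over the alternatives set in advance). That on WRKY53 ended without the first or second clv1-15 or the first or last Ler array (0.06 to 0.10; 0.013 to 0.10 over those set in advance). That on RCA ended without the last clv1-15 or the first Ler array (0.053 to 0.065; 0.0078 to 0.065 over those set in advance). In the remaining lists none passed over all genes, among them the CLE and CLAVATA components (0 of 4, 0 adjusted over the list alone; CLE44, 0.36 ± 0.13, adjusted p = 0.072, 0.042 to 0.25 over the alternatives set in advance; camera adjusted p = 0.75). NRT2.5 had 0.29 ± 0.18 (adjusted p = 0.29). The clock gene GI (-0.21) and 1 of 2 glucosinolate genes (BCAT4, 0.32) passed only when adjusted over the list alone; without the second Ler array BCAT4 passed over all genes (0.017; 0.017 to 0.32 over the alternatives set in advance). Cytokinin response (RR16, 0.34), iron deficiency (AT3G13610, 0.09), secondary wall (GUT2, 0.23), cell cycle (AUR1, -0.10) and touch and wounding (STZ, 0.89) had none past in either way. Only 1 or 2 of the 11 to 20 members of each of these lists were measured.

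Of the 38 lists tested in clv1-15, camera called 5, all up, and none held after adjustment with an estimated correlation. Of 10 extensins 7 rose, with a median of 0.95 (camera adjusted p = 4e-05; adjusted p = 0.31 with an estimated correlation). Cross-hybridisation between such repetitive sequences was not analysed here. Of 106 ribosomal protein probe sets 12 rose and 1 fell, with a median of 0.10 (camera adjusted p = 4.1e-05; adjusted p = 0.31 with an estimated correlation); quantile normalization ended this call. Of 63 plastid-encoded probe sets 8 rose, among them psbM and matK, and 1 fell, rpoA (camera adjusted p = 0.00097; adjusted p = 0.31 with an estimated correlation). The PRA family (2 of 10 rose; camera adjusted p = 0.024; adjusted p = 0.28 with an estimated correlation) was called up. So were the NPF transporters (3 of 21 rose; camera adjusted p = 0.037; adjusted p = 0.28 with an estimated correlation), in which AT3G53960 rose by 0.91 ± 0.19 and AT1G59740 by 0.69 ± 0.12. Class III peroxidases went both ways (6 rose and 5 fell of 41; median 0.01, mean -0.03, test up; camera adjusted p = 0.83), with AT5G64120 at -1.20 ± 0.09, and CC-type glutaredoxins had 1 rise and 1 fall among 8 (camera adjusted p = 0.41). The calls on psbM and rpoA each ended without any 1 of 3 arrays: the first clv1-15 or the first or second Ler array for psbM (adjusted p 0.083 to 0.13; 0.014 to 0.13 over those set in advance), and the second clv1-15 or the first or last Ler array for rpoA (0.072 to 0.086; 0.0017 to 0.086 over those set in advance). Both PRA calls ended as well, PRA1.G1 without the first Ler array (0.063) and PRA1.E without any 1 of 4 arrays, the second or last of clv1-15 and the first or last of Ler (0.052 to 0.14).

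A peptide and a receptor invite the question of whether ligand overexpression and receptor loss oppose one another. AT3G15650 and ATC rose in CLE3ox (1.51 and 1.79) and fell in clv1-15 (-1.84 and -1.89), and SWEET11 did the same. The other named genes of this pattern were AT1G33340, the small heat shock protein gene AT2G29500 and the ubiquitin-conjugating enzyme gene UBC29 (0.45 and -0.47). In the mirror pattern AT3G61400 fell in CLE3ox (-0.86, adjusted p = 0.0072) and rose in clv1-15 (2.30), along with AT5G26080, AT4G37220, the lipid-transfer family gene AT3G53980 and the remorin gene AT5G23750. AT4G33720, AT1G19540 and AT2G38600 rose in both, and AT2G38870, AT5G38900, AT3G18250, CYP71B6 and AT5G38910 fell in both.

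Of 176 probe sets past the threshold in both comparisons 135 (76.7%) changed in opposite directions. Up in CLE3ox and down in clv1-15 were 57, where independent lists would share 14.1 (Fisher's exact test, two-sided, p = 5.86e-21), and down then up were 78 against 15.2 (p = 1.55e-35). Up in both were 12 against 11.6 (Fisher's exact test, p = 0.878), and down in both 29 against 18.6 (p = 0.0145). These exact tests take genes as independent, which they are not. Across all probe sets the effects correlated at r = -0.16 (Spearman -0.13), and at -0.02 among genes that do not differ between Col-0 and Ler. That subset is chosen with the same Col-0 and Ler arrays that are subtracted in the effects, which can by itself raise the correlation. The -0.02 therefore does not show that opposition is absent among these genes. Of the 176, 148 also differ between Col-0 and Ler, and of the other 28, 22 changed in opposite directions. In CLE3ox the calls on AT3G61400 and AT5G23750 ended without the last Col-0 array (adjusted p = 0.051 and 0.055; 0.0016 to 0.054 and 0.0068 to 0.055 over the alternatives set in advance). The CLE3ox call on AT5G26080 ended with the lines as 1 group of 4 arrays (0.058; 0.00082 to 0.058 over those set in advance). That on AT2G38600 ended without any 1 of the 7 arrays (0.062 to 0.17; 0.032 to 0.17 over those set in advance) and that on AT1G19540 without the second array of either line or the first or last Col-0 array (0.061 to 0.088; 0.011 to 0.088 over those set in advance). In clv1-15, AT1G19540 lost its call without the first Ler array (0.055; 0.0077 to 0.055 over those set in advance) and AT2G38600 without the last clv1-15 or second Ler array (0.057 to 0.061; 0.0091 to 0.061 over those set in advance).

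**Figure D2:**
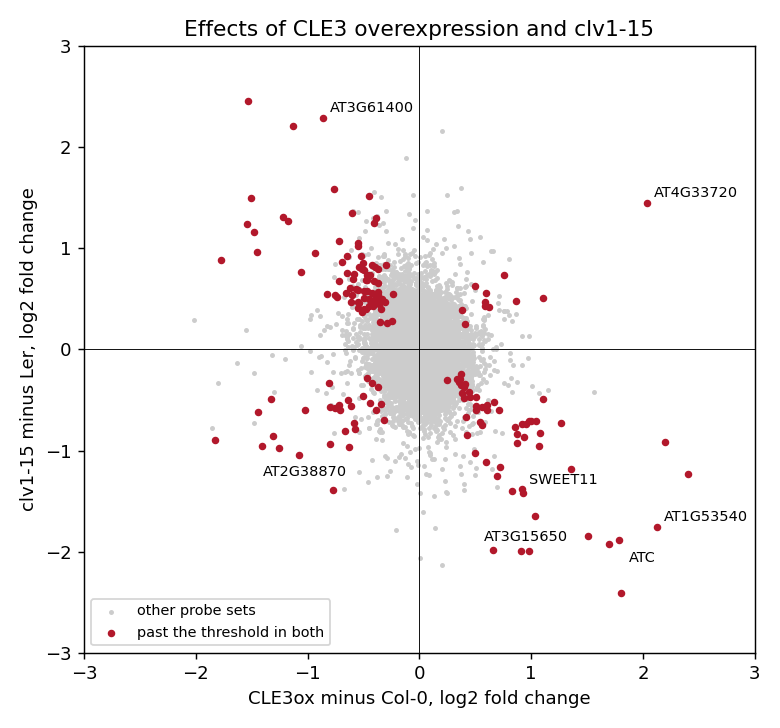
Log2 fold change of CLE3ox against Col-0 (horizontal axis) and of clv1-15 against Ler (vertical axis) for each of the 15922 probe sets (points); 3 lie beyond the axes. The 176 past the threshold in both are red, and 135 of them lie to the upper left or lower right of the origin.

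Tested directly, the CLE3ox effect differed from the clv1-15 effect in 1785 probe sets, 914 higher and 871 lower in CLE3ox. With each array centred on its median it was 714 higher and 1014 lower, so which direction holds more genes depends on the scaling. Among probe sets with a gene name, AT1G53540 (difference of log2 fold changes 3.88 ± 0.40, adjusted p = 1.6e-05), ATC (3.68 ± 0.22, adjusted p = 6.3e-08), AT3G15650, PDF2.1 and AT1G52700 headed the higher side. Some unnamed probe sets differed by more. On the lower side the named ones were headed by AT3G61400 (-3.16 ± 0.23, adjusted p = 6.4e-07), AT3G60270, AT1G26240, AT3G55790 and AT5G14650. Signals of AT3G60270, AT1G26240 and AT3G55790 were only 17.8 ± 4.3, 26.8 ± 5.1 and 6.5 ± 8.3 in Ler. In clv1-15 they were 46.4 ± 7.7, 67.4 ± 2.6 and 15.7 ± 24.5. A fall in clv1-15 could hardly be seen from there, and these differences depend on the pseudocount. The count was 1156 without the first Col-0 array, and 2168 with the spike-in batch as a block.

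The largest rise in CLE3ox lay in a probe set with no gene in the table, from 19.8 ± 16.2 in Col-0 to 11518.2 ± 478.9 and 13338.7 ± 141.3 in the lines, a log2 fold change of 8.57 ± 0.24 (adjusted p = 3.5e-12). It was also higher in clv1-15 (98.5 ± 9.5) than in Ler (20.7 ± 2.1; adjusted p = 0.00061). The deepest fall in clv1-15 was unnamed too, from 1712.3 ± 84 in Ler to 4.4 ± 2.4 (adjusted p = 2e-16), with a rise of 0.67 ± 0.09 in CLE3ox (adjusted p = 0.00046). The largest rise in clv1-15, again unnamed, was 2.46 ± 0.10, against -1.53 ± 0.09 in CLE3ox (adjusted p = 5e-10 and 2.9e-07). Its signal was well above 0, at 908.3 ± 106 in Ler, 5059.6 ± 266.4 in clv1-15 and 1239.1 ± 153.6 in Col-0. In lines 12-1 and 17-3 it was 486 ± 34.9 and 355.4 ± 31.3. What these probe sets measure is not analysed here. The folds of the largest CLE3ox rise and the deepest clv1-15 fall involve signals near 0 and depend on the pseudocount.

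Col-0 was compared with Ler because the CLE3ox lines and clv1-15 stand in different backgrounds. AT5G23830, an MD-2-related lipid recognition gene, had a signal of 3221.4 ± 145 in Col-0 and 15.9 ± 9.8 in Ler (n = 3 each; adjusted p = 4.8e-11). AT1G26380 and AT1G26390 were near 0 in Ler (8.1 ± 8.3 and 15.5 ± 3.2) and at 1494.2 ± 220.2 and 1781.9 ± 301.6 in Col-0. The terpenoid cyclase gene AT3G32030 and AT5G45500 were likewise near 0 in Ler, so the sizes of these folds depend on the pseudocount. AOP3, of glucosinolate side-chain synthesis, was at 852 ± 81.4 in Ler and 20.3 ± 15 in Col-0 (adjusted p = 1.9e-08), and AT4G33720, AT4G31570, AT5G15360 and the terpenoid cyclase gene AT1G70080 were also higher in Ler.

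Between the wild types 7215 probe sets passed (45.3%), 3332 higher and 3883 lower in Col-0, and 1080 differed at least 2-fold; sequence differences under the probes, which can add to such a count, were not analysed here. NRT2.5 was higher in Col-0 by 1.99 ± 0.18 (adjusted p = 2.3e-07), from 50.3 ± 16.5 in Ler to 244.6 ± 47. Of the 32 measured members of fixed lists 10 were higher in Col-0 and 11 lower, and 22 passed when adjusted over the list alone. Higher in Col-0 were both cytokinin response genes, RR16 (1.42 ± 0.17) and ARR15 (0.95 ± 0.19), both root hair expansins, CLE44 (1.32 ± 0.13), AT3G13610, GUT2 and GI. Lower were 3 of 4 early auxin genes, GH3.3, GH3.1 and IAA30, both phloem genes, SWEET11 and OPS, both glucosinolate genes, UGT78D2 (-2.19 ± 0.14), AUR1 and RCA (-1.04 ± 0.12). None of the 3 lateral root genes passed, nor did WRKY53 or STZ. CLE41 was higher and CR4, the receptor kinase gene also known as ACR4, lower (3 of 4 CLE and CLAVATA components in all, 3 adjusted over the list alone; camera adjusted p = 0.99). The calls on CLE41 (without the first Col-0 or last Ler array), CR4 (without the second Col-0 or the first or second Ler array) and BCAT4 (without the first or last Col-0 or the second or last Ler array) ended there, at adjusted p 0.053 to 0.056, 0.058 to 0.074 and 0.068 to 0.25. Over the alternatives set in advance these ran from 0.0018 to 0.056, 0.0076 to 0.074 and 0.013 to 0.25.

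Of the 38 lists, camera called the extensins between Col-0 and Ler (7 of 10 higher in Col-0, median 1.91; camera adjusted p = 5.3e-05; adjusted p = 0.58 with an estimated correlation). Class III peroxidases (15 higher and 9 lower of 41; 0.83), ribosomal proteins (19 and 11 of 106; 0.99), CC-type glutaredoxins (1 and 2 of 8; median 0.10, mean -0.03, test down; 0.99), NPF transporters (8 and 5 of 21; 0.99) and plastid-encoded genes (26 and 9 of 63; 0.12) were not called by camera, nor were the lateral root (0.99) and early auxin (0.31) lists.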

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

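The spike-in batch and its block, and every test on the small heat shock protein genes, were chosen after the data were seen; the splits, the marker runs and the division of the Ler arrays were written before their results.

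The 42 probe sets that differ between lines 17-3 and 12-1, and the 1785 in which the CLE3ox effect differs from the clv1-15 effect, stand here because 2 groups' effects differ in a direct test. The 42 fall to 22 and 14 without the first or second array of line 12-1 and to 13 without the second array of line 17-3. The 1785 fall to 1156 without the first Col-0 array.

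Some small heat shock protein genes were higher in line 17-3 than in line 12-1. Of 19 genes in a list written after the first members were noticed, 9 were measured; 2 passed between the lines, AT1G52560 and AT2G29500, and the median difference was 0.56, with no p for the list since its members prompted it. The call on AT1G52560 ended without the first array of line 12-1 or the second of line 17-3. Of the arrays of line 17-3, 2 of 2 lay above every array of line 12-1 and Col-0 (mean log2 signal 8.44 and 8.49, against at most 7.82), so it is not 1 odd array, but whether these are separate harvests is not stated and an odd harvest stays open. The spike-in batch is argued against, since the line difference was 0.74 in the first batch and 0.66 in the second, and the batch difference within lines 0.09, while handling, insertion site and transgene level of line 17-3 were not analysed here.

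Effects of clv1-15 ran with the wild-type difference: clv1-15 minus Ler had a covariance of 0.0623 with Col-0 minus Ler across probe sets, where sharing the Ler arrays alone gives 0.0083 in simulation. The correlation itself, 0.36, was below the 0.50 of that simulation, which has no true effects to widen the fold changes, so the covariance is the measure read here. With different Ler arrays in each the lowest of 6 covariances was 0.0509, which argues against the shared arrays as the whole source. This division cannot detect a condition common to all Ler arrays. Col-0 chromosome segments in the clv1-15 stock were sought as runs of at least 3 neighbouring Col-0-like markers. There were 0 such runs and the longest run was 2, so 0% of the 1163 placed genes called in clv1-15 could lie in one. The markers are expression differences, and a single marker at the Ler value inside a Col-0 segment would break a run. The test therefore cannot decide on long segments. Only 243 of 430 strong markers, and 20 of the 48 Col-0-like ones, had a position and entered it. The bound for setting segments aside was not met: the 48 (11.2%, against a bound of under 1%) were closer to Col-0. Col-0 segments, long or short, therefore stay open. An effect of clv1-15 itself and conditions common to all Ler arrays stay open as well.

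Of the other 9 splits of the 6 arrays of clv1-15 and Ler the highest called 1 against 2434, and for Col-0 and Ler 0 against 7215. With 10 splits these are too few for a share under 0.05.

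The arrays of the CLE3ox comparison fall into 2 sets by spike-in signal, taken here for a batch, though no label gives a hybridisation date. Of 35 splits of the 7 arrays 1, the real one, called as many as 261 (both lines as 1 group), which argues against a chance division of the arrays. The next, 187, was the split that follows the spike-in batch, which points to a structure of the samples. That batch is argued against as the source of the calls, since 519 passed with it as a block, among them all 389 of the planned fit. Effects of CLE3 overexpression, and conditions shared by both lines and not by Col-0, stay open.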

How the results depend on the processing

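The spike-in batch settings were chosen after seeing the data; the others were planned. No named gene called in the planned fit reversed direction, nor did any called list followed here; the other called probe sets were not followed one by one, and some named genes that were not called, such as WRKY53 and GI in CLE3ox, changed sign. Leaving out each array gave 206 to 375 for CLE3ox, 25 to 54 for line 12-1, 186 to 425 for line 17-3, 13 to 46 between the lines, 1503 to 1888 for clv1-15, 6054 to 6543 for Col-0 against Ler, 1156 to 1750 for the difference of effects and -0.17 to -0.13 for the correlation of the effects. Fewer arrays leave less power. For CLE3ox, 59 passed in each line alone, 51 also at least 2-fold, and 66 and 54 within the first and second spike-in batch. At least 2-fold, 130 remained past for clv1-15 and 1080 for Col-0 against Ler, by construction. Array weights gave 125 for line 12-1, and fitting only the compared groups gave 20 between the lines; the cause was not tested. The correlation was -0.11 with no filter, -0.13 with the lowest 50% left out and -0.02 without genes that differ between Col-0 and Ler; the cause was not tested. List calls over the 3 comparisons numbered 13, against 0 with an estimated correlation and 37 with fry, which asks another question. Blocking on replicate number gave 341, 2390, 7229, 64, 487, 44 and 1617 for CLE3ox, clv1-15, Col-0 against Ler, line 12-1, line 17-3, between the lines and the difference, -0.16 for the correlation and 12 list calls. All other counts stayed within 1.5 times. Of single-gene values with an array left out, 1410 kept their side of the threshold, 153 lost it and 1 gained it; with the block on replicate number 235 kept it, 4 lost it and 1 gained it; under the remaining planned settings 2290 kept it, 73 lost it and 3 gained it; under the spike-in batch settings 244 kept it, 59 lost it and 1 gained it. Between 28.7% and 30.7% of probe sets per array had signals under 50, where MAS5 signal is near background and folds depend on the pseudocount.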

Other observations

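Both gene groups and the division of the Col-0 arrays below were chosen after the result was seen.

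Of 9 measured small heat shock protein genes, 6 rose in CLE3ox, with a median log2 fold change of 0.96 and all 9 positive. In clv1-15 5 fell, with a median of -0.70, and between the wild types 7 were lower in Col-0, with a median of -0.65. No p is given for the list in any comparison, since its members prompted it. In line 17-3 alone 7 rose, while in line 12-1 alone 0 passed in limma, with a median of 0.45 and all 9 positive.

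AT1G26380, AT1G26390 and AT1G26410, berberine bridge enzyme-like oxidase genes, belong to a row of 5 with 0 other protein-coding genes between them in the TAIR10.1 annotation. These 3 measured members fell in CLE3ox, in line 12-1 and in line 17-3 alike. In clv1-15 0 of 3 passed, at signals of at most 10.9 in that mutant and 15.5 in Ler, too low for a fall to be seen.

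The CLE3ox effect ran against the wild-type difference (covariance with Col-0 minus Ler -0.0345), beyond the -0.0083 that the shared Col-0 arrays give in simulation. The correlation, -0.28, was smaller in size than the -0.53 of that simulation, which has no true effects. With different Col-0 arrays in each, 1 in one comparison and 2 in the other, the 6 covariances lay between -0.0295 and -0.019. That argues against the shared arrays as the whole source, with the value nearest 0 only a little beyond 0.5 times the shared one. A condition common to all Col-0 arrays cannot be detected by this division and stays open.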
